A study of Caenorhabditis elegans with 37 samples.

How the data were processed

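RNA-seq measured transcript levels in 37 libraries of sorted C. elegans cells, in 10 groups taken from the sample titles. Per the labels' protocols, worms grew on 8P plates seeded with NA22 bacteria and were not treated. Dissociated cells went through a FACSAria III sorter into Trizol LS, RNA was extracted with chloroform, and libraries were made with the Tecan SoLo Ovation kit. Per the deposited series design text, each sorted type was to be set against other types, a pan-neuronal reference and an all-cell reference.

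The authors deposited raw counts per gene, whole numbers with 1 column per library and no normalization. Per the submitters' processing notes, STAR, SAMtools and featureCounts were used. Their versions, settings, strand use, genome build and treatment of duplicate reads or molecular identifiers are not given in the sources used here. The name under which the counts were deposited carries the WormBase annotation release WS274. The table held 30631 genes, of which 29434 had a count in at least 1 library and 27849 were paired with a symbol. Positions and gene classes were taken from the WBcel235 annotation by gene identifier, which held 30584 of the genes, and were set against no position from the counted annotation. Library totals ran from 251586 to 5415925 counts (median 1638118). Levels are given as CPM, counts scaled by the library total and its TMM factor. Intervals and floors cover counting error only, and the floor for a group with no counts was 3 counts over the group. Fold limits set the mean CPM of the other group against that floor, and count ratios were computed from summed counts and totals.

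Genes were tested in 1 edgeR quasi-likelihood fit over all 37 libraries (edgeR 4.0.16 in R 4.3.3, TMM factors, filterByExpr by group, trended dispersion with a common value of 0.226 and 6.63 prior degrees of freedom). The 27 contrasts set the pan-neuronal against the all-cell group, each of the 8 types against either reference and against the mean of the other types, DD against VD, and AWA against AWB. Of all genes 15181 passed the filter, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts with other types set a log2 level against the mean of the log2 levels of 7 types, which types with few or no counts lower, so their rank is no ratio of means and CPM is printed instead. Log2 differences are printed with their standard errors (± in brackets), CPM values with the SD over libraries. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In pairwise chi-square comparisons of counts, 54 pairs of libraries of the same group differed by 2.22 to 85.9 per degree of freedom, and none were counted as 1 sample. Comparisons with the same reference libraries share their chance values, and overlaps between them are not reported.

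The 33 gene lists cover tissues (pan-neuronal, body-wall and pharyngeal muscle, intestine, hypodermis, germline, sperm, glia, coelomocyte), the markers of each sorted type, the stress response, transmitters, receptors, channels, peptides, cilia, innexins, homeobox factors, ribosomal proteins and histones. They were tested with cameraPR (limma 3.58.1) on the signed square root of the edgeR statistic, with a preset correlation of 0.01 and adjustment within a comparison. List counts are given over the list members tested. The share of counts taken by tissue lists and mitochondrial genes was compared between groups with exact two-sided permutation tests, adjusted over groups. Named genes had an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap between libraries of the compared groups. By rank of log2 difference these were the 12 highest and 10 lowest between the references, the 8 highest and 4 lowest of each type against pan-neuronal libraries, the 5 highest of each type against the others, and 8 each way between paired types. Marker list members and up to 4 members of called lists were added. Groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

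The alternatives were DESeq2 size factors in the edgeR fit, library totals alone, no low-count filter, mitochondrial and ribosomal RNA genes left out (34 mitochondrial genes), the DESeq2 1.42.0 Wald test, fits of the compared groups alone, each library left out in turn in gene and share tests, and an estimated correlation in list tests. Genes to which DESeq2 gave no adjusted p were not counted in that alternative. Leaving out AWA 20 and AWB 51 together, and single libraries in list tests, was added after seeing the data. The gene test was tested on simulated counts drawn from each gene's mean over all libraries and the real totals, with few genes changed. It recovered 45.7% of 94 genes changed 4-fold and 5.49% of 91 changed 2-fold among 13430 genes for pan-neuronal against all-cell libraries. For PVD against pan-neuronal libraries these were 12.5% and 0% of 13485 genes, for DD against VD 37.5% and 1.12% of 13492 genes, and for AWA against AWB 48.5% and 5.68% of 13452 genes. In DD against VD 5.56% of the calls were false (2 calls), and in PVD against other types 11.8% (4 calls). Values were summarised with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.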

Results

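RNA was sequenced from 37 libraries of Caenorhabditis elegans cells isolated by fluorescence-activated cell sorting. The sorts targeted 8 single neuron types, a pan-neuronal reference labelled by a rab-3 marker, and an all-cell reference sorted with stains for living and dead cells alone. The chemosensory neurons ASG, AWA and AWB gave 4, 4 and 5 libraries. The interneurons AVE and AVG gave 3 each, the GABAergic motor neurons DD and VD gave 3 and 4, and the nociceptor PVD gave 2. The pan-neuronal and all-cell references gave 5 and 4 libraries. Total counts ranged from 251586 to 951675 in AWB, the lowest, to 2254581 to 5415925 in VD, the highest, 3124136 to 5252601 in pan-neuronal and 873187 to 1638118 in all-cell libraries.

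**Figure D1:**
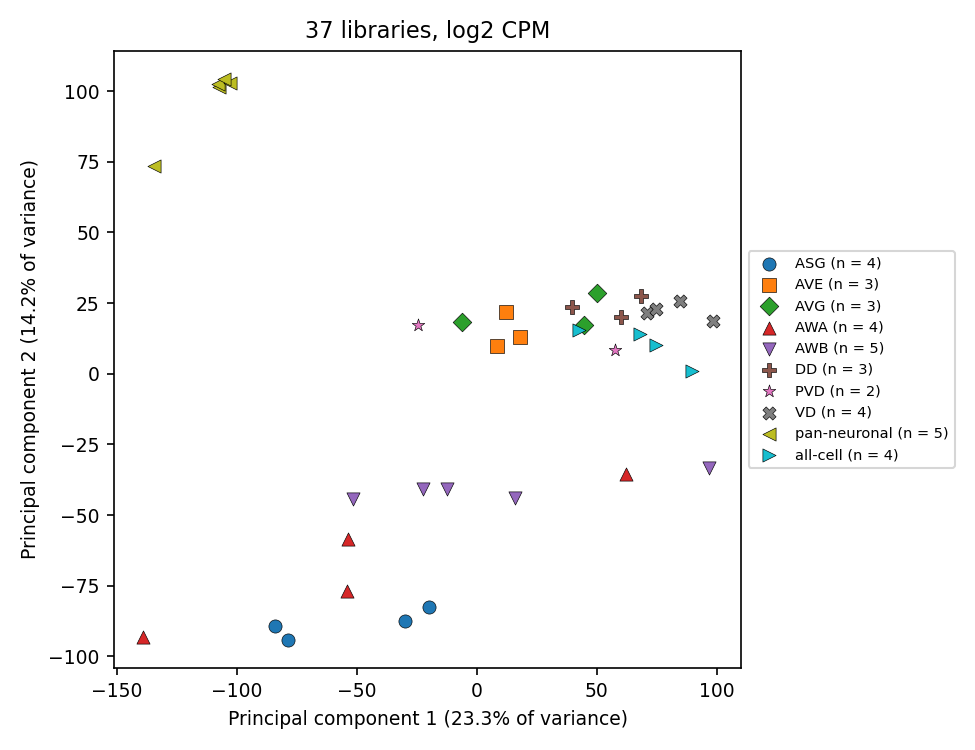
Principal components 1 and 2 of log2 CPM for the 37 libraries, each point being 1 library; the axes carry 23.3% and 14.2% of the variance. The 5 pan-neuronal libraries lie at the top left, the ASG, AWA and AWB libraries lie below 0 on component 2, and AWA 20 and AWB 51 lie to the right of the other libraries of their groups.

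The pan-neuronal libraries were compared with the all-cell libraries, the background against which neuronal signal is read. The pan-neuronal list had 25 of 28 genes higher and 0 lower (25 and 0 adjusted over the list alone, adjusted p = 1.48e-09, or 0.198 with estimated correlation). The FMRFamide-like and other neuropeptides, nicotinic receptor subunits, genes of intraflagellar transport and the cilium, and receptor and soluble guanylyl cyclases had 29 of 30, 52 of 67, 20 of 25, 39 of 44 and 26 of 27 genes higher and 0, 1, 0, 0 and 0 lower (the same over the list). These lists had adjusted p from 2.18e-14 to 6.88e-06, and from 0.0534 to 0.391 with estimated correlation. Homeobox factor and DEG/ENaC channel genes had 59 of 72 and 18 of 22 genes higher and 3 and 1 lower (61 and 18 higher and 4 and 1 lower over the list). As lists they had adjusted p from 2.82e-10 to 9.84e-05, and from 0.0166 to 0.0290 with estimated correlation.

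Of the lists of other tissues, those of germline, sperm, body-wall muscle, hypodermis and intestine were called lower in pan-neuronal libraries, and those of pharyngeal muscle, glia and coelomocytes were not called. The germline, sperm, body-wall muscle and hypodermis lists had 0 of 18, 0 of 8, 1 of 21 and 1 of 20 genes higher and 17, 6, 12 and 12 lower (0, 0, 1 and 2 higher and 17, 7, 13 and 12 lower over the list). Tested as lists these had adjusted p from 1.48e-09 to 0.0352, and from 0.139 to 0.416 with estimated correlation. The sperm call ended with library totals (adjusted p = 0.0797). Ribosomal protein and histone genes had 1 of 77 and 6 of 53 genes higher and 73 and 35 lower (1 and 6 higher and 74 and 38 lower over the list). Their list tests gave adjusted p from 5.31e-17 to 1.56e-05, and from 0.198 to 0.289 with estimated correlation. The intestine list had 0 of 17 genes higher and 3 lower (0 and 0 over the list, adjusted p = 0.0405, or 0.664 with estimated correlation). That call ended with DESeq2 size factors (adjusted p = 0.0520) and with library totals (adjusted p = 0.120), and without all-cell 27 or 28 (adjusted p from 0.0975 to 0.820). Its members vit-3 and vit-4 (log2 differences -2.80 and -2.86) turned to 4.77 and 3.43 without all-cell 27 (edgeR adjusted p = 0.00933 and 0.0308). The stress response list went the other way, with 10 of 13 genes higher and 1 lower (10 and 1 over the list, adjusted p = 1.57e-04, or 0.198 with estimated correlation); its share of counts was 0.152% in pan-neuronal 1 against 1.04% ± 0.512 (SD, n = 5) in the group.

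The lists for GABA synthesis and transport, acetylcholine synthesis and transport, ionotropic glutamate receptors, insulin-like peptides and serpentine chemoreceptors had 4 of 5, 5 of 6, 10 of 12, 16 of 27 and 102 of 268 genes higher and 0, 0, 0, 0 and 10 lower (4, 6, 10, 17 and 93 higher and 0, 0, 0, 1 and 9 lower over the list). These lists had adjusted p from 3.40e-05 to 0.00157, and from 0.0534 to 0.557 with estimated correlation. Of the marker lists of the sorted types, those of ASG, AVE, AVG and AWB had 11 of 11, 7 of 9, 7 of 8 and 7 of 11 genes higher and 0 lower in each (11, 7, 7 and 8 higher and 0 lower in each over the list). As lists they had adjusted p from 7.56e-06 to 0.0389, and from 0.119 to 0.584 with estimated correlation. The AWB marker call ended without pan-neuronal 1, all-cell 27 or 28 (adjusted p from 0.0536 to 0.193) and the chemoreceptor call without pan-neuronal 1 (adjusted p = 0.117). The markers of DD, VD and PVD had 10 of 10, 11 of 11 and 14 of 14 genes higher and 0 lower in each (the same over the list). Tested as lists these had adjusted p from 1.48e-09 to 1.40e-08, and 0.0269 with estimated correlation. List tests were not called for AWA markers (4 of 8 higher, adjusted p = 0.122), innexins (adjusted p = 0.317), pharyngeal muscle (adjusted p = 0.615), glia (adjusted p = 0.659) or coelomocyte genes (adjusted p = 0.132).

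In all, 8966 of 15181 tested genes differed, 4878 higher and 4088 lower in pan-neuronal libraries. The highest ranks were mostly non-coding RNA genes. C18A3.16 (WBGene00196521, chromosome II, 5727769 to 5727959 in the WBcel235 annotation), which overlaps the 5' end of rab-3, stood at 1954 ± 254 CPM (SD, n = 5) in pan-neuronal libraries, a count ratio of 11972 (95% counting interval 2149 to 472888) over all-cell libraries. Its neighbours C18A3.20 and C18A3.18 stood at 1084 ± 163.3 and 1669 ± 220.5 CPM. Reads of overlapping genes cannot be told apart where strand use in counting is not given. F56D12.11, F45E4.17, C48D5.8, F10F2.16, F08H9.14 and F44E5.6 had no counts in all-cell libraries and were higher by at least 157, 137, 96.9, 90.7, 62.1 and 59.1 times. C48D5.8 did not pass the DESeq2 test. K11C4.8 had a count ratio of 737 (95% interval 132 to 29139) and the protein-coding F46A8.7 a count ratio of 2645 (95% interval 475 to 104483), though F46A8.7 reached 1413 CPM in pan-neuronal 1 and at most 186 in the others, and its ratio was 1068 without that library.

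Among the lowest ranks, phat-4, phat-7 and phat-8 were lower in pan-neuronal libraries by log2 differences of -5.44 ± 0.87, -5.19 ± 0.70 and -5.06 ± 0.82 (SE), with all-cell means of 279 ± 192 CPM (SD, n = 4), 442 ± 261 and 84.8 ± 60.1 CPM. dod-6 differed by -5.25 ± 0.69, the RNA-binding protein gene rbm-3.1 by -4.80 ± 0.40, T20G5.8 by -6.36 ± 0.96, the snoRNA gene Y55F3BR.9 by -6.25 ± 0.62 and the ncRNA gene ZK265.11 by -5.07 ± 0.59. F44D12.16 had a count ratio of 711 (95% interval 126.4 to 28190.4) in favour of all-cell libraries. C06E1.7 differed by -9.60 ± 1.43, but its all-cell mean rested on library 27, at 3802 CPM against at most 4.53 in the others. In edgeR the call was lost without all-cell 27 (-1.42, adjusted p = 0.0537). With library totals alone 4068 genes were higher and 5488 lower.

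Summed over each library, the pan-neuronal list took 3.18% ± 0.289 (SD, n = 5) of all counts in pan-neuronal libraries and 0.751% ± 0.446 (SD, n = 4) in all-cell libraries (exact two-sided permutation test, p = 0.00794, adjusted p = 0.0143 over the 9 groups set against pan-neuronal libraries and 0.0714 over the 9 set against all-cell libraries). The share was 1.42% in all-cell 27 and at most 0.581% in the others. Among the sorted types the share ran from 1.13% ± 0.167 (SD, n = 3) in AVE to 2.17% ± 0.341 (SD, n = 4) in ASG. Every library of the 8 types lay below all 5 pan-neuronal libraries (exact permutation adjusted p from 0.0143 to 0.0476). The germline list took 0.673% ± 0.295 (SD, n = 4) in all-cell and 0.0910% ± 0.0155 (SD, n = 5) in pan-neuronal libraries (exact permutation adjusted p = 0.0357). The hypodermis share was 0.332%, 0.540%, 0.393%, 0.396% and 0.691% in AVE, AVG, AWB, DD and VD against 0.108% ± 0.0278 (SD, n = 5), each library lying above all 5 pan-neuronal ones (exact permutation adjusted p from 0.0238 to 0.0268). The intestine share passed in ASG, AVE, AWB, DD and VD (0.161% to 0.456% against 0.0481%, exact permutation adjusted p from 0.0402 to 0.0429), and the pharyngeal muscle share in AVE, AWB, DD and VD (0.0550% to 0.139% against 0.0165%, exact permutation adjusted p = 0.0402). The germline share passed in AVE, AVG and VD (0.183% to 0.230% against 0.0910%, exact permutation adjusted p from 0.0357 to 0.0402). That rise was mostly mex-3 in AVE and mostly pie-1 in AVG. The coelomocyte share passed in AWB and VD (0.00433% and 0.0294% against 0.00144%, exact permutation adjusted p = 0.0357), where VD 78 stood at 0.0653% and the other VD libraries at most at 0.0261%. Body-wall muscle, sperm and glia shares passed in no type; the lowest p for body-wall muscle was in AVE, DD and VD (exact permutation adjusted p = 0.0536 in each), with 2.92% ± 0.149 (SD, n = 3) in AVE against 1.18% ± 0.119 (SD, n = 5). Mitochondrial genes took 3.90% ± 1.26 (SD, n = 5) in AWB against 1.75% ± 0.397 (SD, n = 5) in pan-neuronal libraries (exact permutation adjusted p = 0.0357). In 198 such tests over 11 shares, 36 passed. PVD, with 2 libraries, could reach no exact p below 0.0476 against pan-neuronal and 0.0667 against all-cell libraries. Without each pan-neuronal library in turn 14 tests passed.

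Set against all-cell libraries, each of the 8 types had the pan-neuronal list called higher. In the order ASG, AVE, AVG, AWA, AWB, DD, PVD and VD, 19, 14, 18, 18, 14, 22, 17 and 17 of 28 genes were higher and 1 lower in ASG, with 0 lower in the others (20, 16, 22, 19, 14, 22, 17 and 18 higher and 1, 0, 0, 0, 2, 0, 0 and 0 lower over the list). The adjusted p ran from 4.22e-15 to 7.05e-04, and from 0.252 to 0.952 with estimated correlation. The share of counts of this list passed in no type (exact permutation adjusted p from 0.0857 to 0.257); in AVE no library lay above all 4 all-cell libraries, and 1 of the 5 AWB libraries lay below them.

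ASG, an amphid chemosensory neuron, was compared with pan-neuronal libraries to find its enriched genes. Genes of intraflagellar transport and the cilium were higher, with 38 of 44 genes higher and 1 lower (39 and 1 over the list, adjusted p = 8.85e-19, or 0.0910 with estimated correlation). ASG markers had 7 of 11 genes higher and 2 lower (7 and 2 over the list, adjusted p = 0.00848, or 0.255 with estimated correlation). The receptor guanylyl cyclase genes gcy-21 (WBGene00001546, chromosome II, 2659664 to 2664686) and gcy-15 stood at 8645 ± 2958 CPM (SD, n = 4) and 6809 ± 2251 CPM against 186 ± 155 and 206 ± 162 in pan-neuronal libraries (log2 differences 5.54 ± 0.61 and 5.05 ± 0.55, SE). ops-1 differed by 5.85 ± 0.67, and the cyclic nucleotide-gated channel subunits tax-2 and tax-4 by 3.62 ± 0.54 and 3.70 ± 0.61. The homeobox genes lin-11 (1.25 ± 0.47) and unc-30 (1.28 ± 0.40) passed, but edgeR no longer called lin-11 without ASG 13 or 14 (1.02 to 1.15, adjusted p from 0.0767 to 0.117) or pan-neuronal 7, 10, 11 or 12 (1.15 to 1.27, adjusted p from 0.0521 to 0.0753), nor unc-30 without ASG 13 (1.04, adjusted p = 0.0613). The peptide genes flp-6 and flp-13 fell by 4.53 and 6.18 on the log2 scale, and eat-4 and flp-22 did not pass. By rank, Y37H2A.14, pha-1, F21C10.11, Y68A4A.13, the acyl-CoA dehydrogenase gene acdh-1, T26H5.9, scl-8 and the desaturase gene fat-7 were higher, with log2 differences from 6.11 (fat-7) to 8.41 (Y37H2A.14). pha-1 stood at 1026 ± 445 CPM (SD, n = 4) against 6.27 ± 3.50. T22F3.11 was at least 103.6-fold lower. In ASG the lists of body-wall muscle and intestine were called higher, with 13 of 21 and 7 of 17 genes higher and 1 and 0 lower (14 and 7 higher and 1 and 0 lower over the list). Their list tests gave adjusted p from 5.59e-04 to 0.00162, and from 0.503 to 0.615 with estimated correlation. The body-wall muscle call ended without ASG 15 (adjusted p = 0.0749). The ASG contrast with pan-neuronal libraries called 5709 genes, 2556 higher and 3153 lower.

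Against the other 7 types, K02F6.8 (326 ± 147 CPM against 1.91, the highest mean of another type, as in all such contrasts below), ZC132.3 (1057 ± 407 against 4.26) and gcy-21 (8645 ± 2958 against 23.6) ranked among the highest in ASG. ASG markers had 9 of 11 genes higher and 1 lower (9 and 1 over the list, adjusted p = 9.76e-28, or 0.0312 with estimated correlation). The ASG contrast with the mean of the other 7 types called 4507 genes, 2541 higher and 1966 lower, or 1798 and 3216 with library totals. The ASG contrast with all-cell libraries called 6048 genes, 2976 higher and 3072 lower, or 2082 and 5232 with library totals, 3263 and 2641 without mitochondrial and rRNA genes, 3110 and 2473 with no low-count filter. That total was 4002 (2099 higher and 1903 lower) with these groups fitted alone.

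AVE, a command interneuron, had a marker list that was not called against pan-neuronal libraries, with 0 of 9 genes higher and 2 lower (0 and 2 over the list, adjusted p = 0.9502, or 0.934 with estimated correlation). The glutamate receptor genes glr-1, glr-2 and nmr-1 differed by 1.23 ± 0.64, -0.11 ± 0.75 and -0.25 ± 0.58 (SE), none past the threshold. The vesicular acetylcholine transporter gene unc-17 (-1.69 ± 0.57) and the choline transporter gene cho-1 (-2.35 ± 0.54) were lower, but unc-17 lost its edgeR call without AVE 40 or 41 (-1.72 to -1.56, adjusted p from 0.0617 to 0.0890). Ribosomal protein genes were higher, with 76 of 77 genes higher and 0 lower (77 and 0 over the list, adjusted p = 1.49e-64, or 0.0483 with estimated correlation). C06E1.7 (WBGene00015522, chromosome III, 8591271 to 8593720) ranked highest at 4303 ± 947 CPM (SD, n = 3) against 1.10 ± 0.904 (log2 difference 11.78, SE 1.55, edgeR adjusted p = 9.96e-07). With fip-3, fipr-16 and C06E1.12 it lies upstream of glr-1. C06E1.7 also stood at 3802 CPM in all-cell 27. The fungus-induced protein genes fip-3 and fipr-16 differed by 10.34 ± 1.67 and 9.26 ± 1.42, R03H10.6 by 8.35 ± 0.88 and T27A3.11, next to pept-3, by 7.82 ± 0.80. C54F6.17 was at least 237-fold higher, ZK177.9 had a count ratio of 499.7 (95% interval 87.2 to 19976), or 238 without AVE 40 and 766 without AVE 42, and C06E1.12 a count ratio of 1533 (95% interval 422 to 12691). The aquaporin gene aqp-12, T21H3.5, F45E4.17 and F46A8.7 had no counts in AVE and were lower by at least 63.3, 89.1, 66.9 and 419 times (171 without pan-neuronal 1). In AVE the lists of body-wall muscle, pharyngeal muscle, hypodermis, intestine and germline were called higher, with 13 of 21, 2 of 6, 6 of 20, 4 of 17 and 3 of 18 genes higher and 0, 0, 1, 0 and 0 lower (15, 3, 10, 0 and 3 higher and 1, 0, 2, 0 and 0 lower over the list). These lists had adjusted p from 8.58e-05 to 0.0337, and from 0.441 to 0.612 with estimated correlation. The pharyngeal muscle call ended without AVE 42 (adjusted p = 0.0561) and the germline call without pan-neuronal 1 (adjusted p = 0.0753). The germline gene mex-3 stood at 1126 ± 289 CPM (SD, n = 3) against 52.8 ± 9.69. The AVE contrast with pan-neuronal libraries called 5101 genes, 1982 higher and 3119 lower. That total was 7762 with these groups fitted alone.

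In AVE set against the other types, AVE markers had 9 of 9 genes higher and 0 lower (9 and 0 over the list, adjusted p = 6.14e-17, or 0.0487 with estimated correlation). C06E1.7 (4303 ± 947 against 5.15), fipr-16 (208 ± 53.97 against 0.789) and fip-3, at 429.9 ± 111 CPM (SD, n = 3), ranked highest, T27A3.11 was at least 1185-fold higher (681 without AVE 42) and C06E1.12 had a count ratio of 8224 (95% interval 1469 to 325486). The AVE contrast with the mean of the other 7 types called 2083 genes, 1571 higher and 512 lower. That total was 1012 without AVE 40. The AVE contrast with all-cell libraries called 2327 genes, 1297 higher and 1030 lower, or 1154 and 1193 with DESeq2 size factors, 1000 and 1524 with library totals, 1418 and 1687 with the DESeq2 test, 749 and 1070 with these groups fitted alone. That total was 986 without AVE 40, 1269 without AVE 42, 1176 without all-cell 29 and 1384 without all-cell 30.

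AVG, the interneuron that pioneers the ventral nerve cord, had higher transcripts of the innexin gene inx-18 (WBGene00002140, chromosome IV, 606355 to 614062), at 81.1 ± 35.6 CPM (SD, n = 3) against 6.21 ± 4.17 in pan-neuronal libraries (log2 difference 3.68, SE 0.51, edgeR adjusted p = 2.10e-06). The glutamate receptor gene nmr-1 was also higher (2.98 ± 0.57, SE). glr-1 (2.58 ± 0.65) lost its edgeR call without AVG 45 (1.60, adjusted p = 0.0824), and lin-11 (1.41 ± 0.50) without AVG 44 or 45 (0.89 to 1.34, adjusted p from 0.0797 to 0.237) or pan-neuronal 10, 11 or 12 (1.22 to 1.39, adjusted p from 0.0514 to 0.0828). AVG markers had 4 of 8 genes higher and 2 lower (4 and 2 over the list, adjusted p = 0.198, or 0.623 with estimated correlation), and the list was not called. unc-17 and cho-1 fell by 3.74 and 4.20 on the log2 scale, and odr-2 and ast-1 did not pass. By rank, F40G12.2 (6.70 ± 0.65), the snoRNA gene Y55F3BR.9 (7.08 ± 0.65), M163.12 (7.72 ± 1.08), M163.15 (7.08 ± 1.14), ZK265.11 (6.59 ± 0.63) and K09C6.2 (6.38 ± 0.85) were higher. Y49E10.30 had a count ratio of 341 (95% interval 91.1 to 2870.3) and H06I04.8 a count ratio of 182 (95% interval 47.2 to 1558), or 299.7 without AVG 43. The acyl-CoA-binding protein gene acbp-7 was at least 78.8-fold lower, and C18A3.20 at least 706-fold lower. In AVG the lists of body-wall muscle, hypodermis, germline and intestine were called higher, with 14 of 21, 11 of 20, 7 of 18 and 3 of 17 genes higher and 1, 0, 0 and 0 lower (15, 15, 8 and 0 higher and 1, 0, 0 and 0 lower over the list). As lists they had adjusted p from 9.88e-06 to 0.00143, and from 0.166 to 0.436 with estimated correlation. The cuticle collagen gene dpy-13 stood at 678 ± 124 CPM (SD, n = 3) against 100.4 ± 54.2, and the germline gene pie-1 at 995 ± 497 against 27.2 ± 7.76. The body-wall muscle share did not pass (exact permutation adjusted p = 0.268). The AVG contrast with pan-neuronal libraries called 4768 genes, 1773 higher and 2995 lower.

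In AVG set against the other types, AVG markers had 6 of 8 genes higher and 0 lower (6 and 0 over the list, adjusted p = 8.04e-24, or 0.00785 with estimated correlation). Stress response genes had 6 of 13 genes higher and 0 lower (8 and 1 over the list, adjusted p = 1.31e-04, or 0.379 with estimated correlation). F40G12.2 (220 ± 97.1 against 1.09), the chemoreceptor gene srd-3 (44.7 ± 32.7 against 0.511) and T10G3.8 (584 ± 269.6 against 3.86) ranked among the highest. The AVG contrast with the mean of the other 7 types called 1748 genes, 1099 higher and 649 lower, or 975 and 1022 with library totals. That total was 1094 without AVG 44 and 986 without AVG 45. The AVG contrast with all-cell libraries called 3065 genes, 1588 higher and 1477 lower, or 1236 and 2620 with library totals, 1748 and 1753 with the DESeq2 test, 1766 and 1880 without AWA 20 and AWB 51, a choice made after seeing the data. That total was 1801 without AVG 45, and 1384 with these groups fitted alone.

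AWA, an olfactory neuron, had a marker list higher than in pan-neuronal libraries, with 8 of 8 genes higher and 0 lower (8 and 0 over the list, adjusted p = 1.26e-09, or 0.0270 with estimated correlation). odr-10 (WBGene00003856, chromosome X, 6864315 to 6865939), which encodes the diacetyl receptor, stood at 5743 ± 5236 CPM (SD, n = 4) against 90.7 ± 177 (log2 difference 5.98, SE 0.94, edgeR adjusted p = 5.35e-06). Its pan-neuronal level was 407 CPM in library 1 and at most 15.9 in the others. Without pan-neuronal 1 the log2 differences of odr-10, ocr-2, str-44, srj-11 and nlp-23 were 8.93, 5.76, 9.60, 11.68 and 9.48. The TRPV channel genes ocr-1, ocr-2 and osm-9 differed by 7.98 ± 0.73, 3.96 ± 0.67 and 4.31 ± 0.57, the nuclear receptor gene odr-7 by 6.41 ± 0.82 and the G protein genes odr-3 and gpa-6 by 4.36 ± 0.70 and 4.71 ± 0.62. Cilium genes had 35 of 44 genes higher and 1 lower (36 and 1 over the list, adjusted p = 7.16e-10, or 0.209 with estimated correlation). Y116A8C.40 had a count ratio of 19681 (95% interval 3531 to 777463) and K09C4.7 a count ratio of 456 (95% interval 125 to 3779.7). The chemoreceptor genes str-44 (6.53 ± 1.08), srt-7 (7.35 ± 0.81), srj-11 (7.34 ± 0.94) and srt-12 (7.08 ± 0.84), the peptide gene nlp-23 (7.24 ± 0.88) and B0432.1 (7.24 ± 0.65) were higher; reads of near-identical chemoreceptor paralogs leave their values uncertain. Of 268 tested chemoreceptor genes, 115 were higher and 58 lower in AWA (184 either way over the list, adjusted p = 0.00149, adjusted p = 0.473 with estimated correlation), and with no low-count filter the direction reversed (adjusted p = 0.909). In AWA the lists of body-wall muscle and intestine were called higher, with 10 of 21 and 11 of 17 genes higher and 0 lower in each (10 and 14 higher and 0 lower in each over the list). Tested as lists these had adjusted p from 7.92e-04 to 0.0328, and from 0.575 to 0.739 with estimated correlation. Both calls ended without AWA 20 (adjusted p = 0.207 and 0.104), whose intestine share was 1.58% against at most 0.260% in the other AWA libraries. The AWA contrast with pan-neuronal libraries called 5744 genes, 2743 higher and 3001 lower, or 3647 and 2768 with library totals, 3179 and 3111 with the DESeq2 test.

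Against the other 7 types, insulin-like peptide genes were higher in AWA, with 20 of 27 genes higher and 0 lower (21 and 0 over the list, adjusted p = 5.79e-32, or 0.0376 with estimated correlation). AWA markers had 8 of 8 genes higher and 0 lower (8 and 0 over the list, adjusted p = 5.02e-35, or 0.0123 with estimated correlation). The chemoreceptor genes str-44 (1082 ± 1229 against 20.5), srx-56 (775 ± 549 against 3.85) and str-261 (300 ± 253 against 3.33) ranked among the highest, and srt-14 had a count ratio of 882 (95% interval 299.8 to 4292), or 553 without AWA 17. The AWA contrast with the mean of the other 7 types called 2694 genes, 2009 higher and 685 lower. The AWA contrast with all-cell libraries called 4926 genes, 2854 higher and 2072 lower, or 2440 and 2667 with library totals. That total was 2172 with these groups fitted alone.

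AWB, an olfactory neuron of the amphid, had its marker list higher than in pan-neuronal libraries, with 11 of 11 genes higher and 0 lower (11 and 0 over the list, adjusted p = 9.95e-13, or 0.0688 with estimated correlation). The chemoreceptor gene str-220 (WBGene00006251, chromosome IV, 7169931 to 7171322) stood at 845 ± 669 CPM (SD, n = 5) against 0.525 ± 0.204 (log2 difference 10.56, SE 0.83, edgeR adjusted p = 2.86e-08), str-1 differed by 8.16 ± 0.91 and srd-23 by 6.62 ± 0.96 (9.82 without pan-neuronal 1). The guanylyl cyclase genes odr-1 and daf-11 differed by 4.76 ± 0.61 and 5.40 ± 0.64, tax-2 by 4.21 ± 0.54, and the homeobox genes lim-4 and ceh-37 by 3.01 ± 0.55 and 3.29 ± 0.54. Cilium genes had 16 of 44 genes higher and 1 lower (15 and 1 over the list, adjusted p = 8.60e-04, or 0.489 with estimated correlation). srd-13 was at least 215-fold higher, and str-243 (7.95 ± 0.95), srv-31 (7.82 ± 0.91) and srg-64 (7.64 ± 0.95) were higher. Y116A8C.40 had a count ratio of 835 (95% interval 148 to 33222) and H06I04.8 a count ratio of 364 (95% interval 98.7 to 3042). The chemoreceptor list had 80 of 268 genes higher and 52 lower (81 and 55 over the list, adjusted p = 0.0264, or 0.489 with estimated correlation), whose call ended with DESeq2 size factors (adjusted p = 0.0730) and with library totals (adjusted p = 0.0845), and without pan-neuronal 7, 10 or 12 (adjusted p from 0.0548 to 0.0617), and whose direction reversed with no low-count filter (adjusted p = 0.942). In AWB the lists of body-wall muscle, pharyngeal muscle and hypodermis were called higher, with 14 of 21, 5 of 6 and 11 of 20 genes higher and 1, 0 and 1 lower (14, 5 and 12 higher and 1, 0 and 1 lower over the list). Their list tests gave adjusted p from 1.90e-05 to 0.0293, and from 0.287 to 0.489 with estimated correlation. The pharyngeal muscle call ended without AWB 51 (adjusted p = 0.229). The hypodermis genes noah-2 and wrt-10 differed by 3.94 ± 0.66 and 3.56 ± 0.54. The body-wall muscle, pharyngeal muscle and intestine shares were 3.89%, 0.407% and 0.372% in AWB 51 and at most 1.75%, 0.0612% and 0.163% in the other AWB libraries, and the first did not pass against pan-neuronal libraries (exact permutation adjusted p = 0.582). The AWB contrast with pan-neuronal libraries called 6634 genes, 2982 higher and 3652 lower, or 3412 and 3304 with DESeq2 size factors, 3613 and 3187 with library totals, 3697 and 3334 with the DESeq2 test.

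Against the other 7 types, AWB markers had 11 of 11 genes higher and 0 lower (11 and 0 over the list, adjusted p = 7.79e-64, or 0.0611 with estimated correlation). str-220 had a count ratio of 46899 (95% interval 8411 to 1853010.0), and str-1 (148 ± 103.9 against 0.330) and srt-62 (278 ± 212 against 0.840) were among the next. The AWB contrast with the mean of the other 7 types called 2635 genes, 1732 higher and 903 lower, or 2103 and 596 with DESeq2 size factors. The AWB contrast with all-cell libraries called 5098 genes, 2468 higher and 2630 lower, or 2696 and 2387 with DESeq2 size factors, 2057 and 3308 with library totals, 2679 and 2379 without mitochondrial and rRNA genes, 2397 and 1859 with no low-count filter, 2945 and 2572 with the DESeq2 test. That total was 2860 with these groups fitted alone.

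DD, a GABAergic motor neuron class of the ventral cord, had higher transcripts of unc-25 (WBGene00006762, chromosome III, 12942651 to 12949883), which encodes glutamate decarboxylase. It stood at 4535 ± 917 CPM (SD, n = 3) against 1033 ± 53.4 (log2 difference 2.13, SE 0.31, edgeR adjusted p = 3.12e-06). The vesicular GABA transporter gene unc-47 differed by 2.57 ± 0.32, unc-46 by 2.51 ± 0.39, and the homeobox genes unc-30 and irx-1 by 3.01 ± 0.43 and 2.10 ± 0.41. DD markers and genes of GABA synthesis and transport had 6 of 10 and 3 of 5 genes higher and 2 and 1 lower (the same over the list). These lists had adjusted p from 0.00128 to 0.00629, and from 0.164 to 0.165 with estimated correlation. ttr-39 was higher (2.18 ± 0.38), while the GABA transporter gene snf-11 and the peptide gene flp-11 fell by 2.20 and 2.70 on the log2 scale. By rank, the LIM homeobox gene ttx-3 stood at 1071 ± 250.1 CPM (SD, n = 3) against 18.7 ± 9.93, and ttbk-5 (5.68 ± 0.51), idpp-12 (6.98 ± 1.07, or 2.52 without DD 83) and F33D4.11 (5.82 ± 0.83), upstream of flp-13, were higher. F33D4.11 did not pass the DESeq2 test. W08E12.2 (7.51 ± 1.25), W08E12.4 (6.63 ± 1.19), the asparagine synthetase gene asns-1 (6.49 ± 1.11) and abu-11 (5.76 ± 0.94) lost their edgeR calls without DD 83, where their differences were 2.50, 2.24, 2.35 and 1.41. D2089.7 was at least 228-fold lower. In DD the lists of body-wall muscle, pharyngeal muscle, hypodermis, intestine and germline were called higher, with 16 of 21, 5 of 6, 13 of 20, 10 of 17 and 4 of 18 genes higher and 0 lower in each (17, 5, 13, 10 and 2 higher and 0 lower in each over the list). As lists they had adjusted p from 1.01e-06 to 0.0478, and from 0.204 to 0.617 with estimated correlation. The germline call ended without DD 84, pan-neuronal 1, 7 or 10 (adjusted p from 0.0529 to 0.645). It also ended without mitochondrial and rRNA genes (adjusted p = 0.0516). The DD contrast with pan-neuronal libraries called 5936 genes, 2774 higher and 3162 lower, or 3647 and 2743 with library totals, 2088 and 3686 without mitochondrial and rRNA genes.

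In DD set against the other types, which include VD, DD markers had 8 of 10 genes higher and 0 lower (8 and 0 over the list, adjusted p = 4.77e-129, or 1.91e-07 with estimated correlation). F33D4.11 (63.7 ± 21.8 against 10.5), ttx-3 (1071 ± 250.1 against 503), ttr-39 (1344 ± 276 against 831) and unc-46 (299 ± 69.4 against 167) ranked among the highest. The DD contrast with the mean of the other 7 types called 832 genes, 570 higher and 262 lower, or 475 and 395 with DESeq2 size factors. That total was 427 without DD 83 and 457 without DD 86, and 1314 (520 higher and 794 lower) with the DESeq2 test, 1582 without AWA 20 and AWB 51. The DD contrast with all-cell libraries called 2915 genes, 1647 higher and 1268 lower, or 1371 and 1783 with DESeq2 size factors, 1418 and 1554 with library totals, 1626 and 2419 with the DESeq2 test. That total was 1369 without DD 83, 1775 without DD 86, 1660 without all-cell 29 and 1924 without all-cell 30, and 1724 with these groups fitted alone.

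PVD, a branched nociceptor, had higher transcripts of des-2 (WBGene00000955, chromosome V, 11415272 to 11421705) and deg-3, which encode nicotinic receptor subunits. They stood at 3808 ± 1323 CPM (SD, n = 2) and 2120.0 ± 791 CPM against 101 ± 23.3 and 60.8 ± 6.31 in pan-neuronal libraries (log2 differences 5.24 ± 0.50 and 5.12 ± 0.46, SE). The dendrite receptor gene dma-1 differed by 3.50 ± 0.46, hpo-30 by 3.50 ± 0.41, the tyramine receptor gene ser-2 by 4.34 ± 0.57, the LIM homeobox gene mec-3 by 3.25 ± 0.54 and mec-10 by 2.54 ± 0.50. PVD markers had 8 of 14 genes higher and 2 lower (10 and 2 over the list, adjusted p = 3.54e-09, or 0.0558 with estimated correlation). del-1 (2.26 ± 0.55) lost its edgeR call without PVD 63 (1.46, adjusted p = 0.148). zag-1 fell by 3.56 on the log2 scale, and degt-1, with no counts in PVD, was at least 10.7-fold lower, an edgeR call lost without PVD 62 (adjusted p = 0.0580). By rank, T01B7.11, next to rol-6, had a count ratio of 3324 (95% interval 1133 to 16153), or 5061 without PVD 62, C02D4.6, upstream of ser-2, a count ratio of 405 (95% interval 134 to 1998) and C02D4.7 a count ratio of 177 (95% interval 56.3 to 891); the last pair did not pass the DESeq2 test. acp-7 (7.46 ± 0.72), M163.12 (7.27 ± 1.13), Y55F3BR.9 (6.74 ± 0.69) and F01D5.12 (6.47 ± 0.89) were higher, and M163.15 (6.49 ± 1.20) lost its edgeR call without PVD 62 (5.29, adjusted p = 0.0797). C35B1.7 was at least 39.9-fold lower. In PVD the lists of body-wall muscle, hypodermis and intestine were called higher, with 4 of 21, 5 of 20 and 4 of 17 genes higher and 0, 1 and 0 lower (9, 7 and 4 higher and 1, 1 and 0 lower over the list). These lists had adjusted p from 8.29e-04 to 0.0101, and from 0.451 to 0.702 with estimated correlation. The intestine call ended without PVD 62. The hypodermis gene rol-6 stood at 534 ± 72.4 CPM (SD, n = 2) against 17.4 ± 7.43, with 1118 CPM in AVE (source not tested). Both PVD libraries exceeded all 5 pan-neuronal ones in shares of body-wall muscle (2.10% ± 0.00669), hypodermis (0.349% ± 0.210), intestine (0.167% ± 0.125) and mitochondrial genes (4.62% ± 1.29), but none passed (exact permutation adjusted p from 0.0612 to 0.107). The PVD contrast with pan-neuronal libraries called 3436 of 15181 genes, 1343 higher and 2093 lower in PVD, or 2026 and 1777 with library totals. That total was 965 without PVD 62, and 5569 with these groups fitted alone.

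In PVD set against the other types, PVD markers had 12 of 14 genes higher and 0 lower (12 and 0 over the list, adjusted p = 1.02e-135, or 1.49e-06 with estimated correlation). T01B7.11 (620.3 ± 299 against 22.7), Y48G10A.6 (4957 ± 3547 against 8.82) and the chemoreceptor gene srh-74 (129 ± 64.98 against 0.474) ranked among the highest, with C02D4.6 at a count ratio of 1681 (95% interval 453 to 14087) and C02D4.7 at least 515-fold higher, neither passing the DESeq2 test. The PVD contrast with the mean of the other 7 types called 796 genes, 672 higher and 124 lower. That total was 371 without PVD 63. The PVD contrast with all-cell libraries called 2778 genes, 1552 higher and 1226 lower. That total was 1717 without PVD 62 and 838 without PVD 63, and 1332 with these groups fitted alone.

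VD, the other GABAergic motor neuron class sorted, also had higher unc-25 transcripts. They stood at 2552 ± 601 CPM (SD, n = 4) against 1033 ± 53.4 (log2 difference 1.30, SE 0.29, edgeR adjusted p = 3.61e-04), unc-47 differed by 1.78 ± 0.30, unc-46 by 1.66 ± 0.37, unc-30 by 2.04 ± 0.41 and ttr-39 by 1.48 ± 0.36. VD markers and genes of GABA synthesis and transport had 5 of 11 and 3 of 5 genes higher and 1 lower in each (the same over the list). Neither list was called (adjusted p from 0.0850 to 0.175, and 0.416 with estimated correlation). snf-11 fell by 2.26 on the log2 scale, and unc-55, oig-1, alr-1, acr-12 and irx-1 did not pass. By rank, Y116A8C.3 (6.93 ± 0.84), Y73F4A.1 (5.91 ± 0.78), the collagen gene col-41 (5.82 ± 0.70), C52D10.3 (5.74 ± 0.88), F33H12.7 (5.73 ± 1.08), the bZIP gene zip-8 (5.68 ± 0.81), the hedgehog-related gene qua-1 (5.65 ± 0.67) and cof-2 (5.49 ± 0.68) were higher. Y116A8C.3, Y73F4A.1, zip-8, cof-2 and F33H12.7 were at 241, 422, 240, 156 and 48.9 CPM in VD 78 and at most 81.8, 151, 44.3, 34.0 and 14.2 in the others. F45E4.17 and C48D5.8 were at least 421- and 298-fold lower, the latter not passing the DESeq2 test. In VD the lists of body-wall muscle, hypodermis, intestine, germline and coelomocyte were called higher, with 18 of 21, 15 of 20, 10 of 17, 7 of 18 and 3 of 3 genes higher and 0 lower in each (18, 16, 10, 7 and 3 higher and 0 lower in each over the list). These lists had adjusted p from 4.26e-06 to 0.0253, and from 0.170 to 0.539 with estimated correlation. The germline call ended without VD 79 (adjusted p = 0.0800). The VD contrast with pan-neuronal libraries called 8538 genes, 4206 higher and 4332 lower, or 5185 and 3689 with library totals, 3184 and 5184 without mitochondrial and rRNA genes, 4560 and 4518 without AWA 20 and AWB 51. That total was 13265 with no low-count filter.

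In VD set against the other types, which include DD, VD markers had 9 of 11 genes higher and 0 lower (10 and 0 over the list, adjusted p = 2.37e-70, or 7.80e-05 with estimated correlation). Coelomocyte genes had 3 of 3 genes higher and 0 lower (3 and 0 over the list, adjusted p = 2.76e-13, or 0.0533 with estimated correlation). zip-8 (78.98 ± 108 against 2.08), the C-type lectin gene clec-178 (59.8 ± 52.8 against 3.45) and the ligand-gated channel gene lgc-28 (69.8 ± 73.3 against 4.68) ranked among the highest. The VD contrast with the mean of the other 7 types called 3145 genes, 2110 higher and 1035 lower, or 1288 and 1437 with DESeq2 size factors, 1280 and 1440 without mitochondrial and rRNA genes, 1454 and 2258 with the DESeq2 test. That total was 1908 without VD 77 and 1914 without VD 79, and 5218 without AWA 20 and AWB 51. The VD contrast with all-cell libraries called 3243 genes, 1998 higher and 1245 lower, or 1470 and 1988 with DESeq2 size factors, 1459 and 1570 with library totals, 1679 and 1665 without mitochondrial and rRNA genes, 1876 and 2671 with the DESeq2 test. That total was 1860 without VD 78, 2013 without VD 81, 1507 without all-cell 29 and 1939 without all-cell 30.

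DD and VD share the GABA transmitter and most of their fixed markers, and were compared directly. The peptide gene flp-13, at WBGene00001456, chromosome IV, 7696932 to 7698420, stood at 1205 ± 518 CPM (SD, n = 3) in DD and 236 ± 78.7 CPM (SD, n = 4) in VD (log2 difference 2.35, SE 0.48, edgeR adjusted p = 0.0210), and it was the called member of the DD markers, which had 1 of 10 genes higher and 0 lower (2 and 0 over the list, adjusted p = 2.09e-09, or 0.00783 with estimated correlation). F59B10.3, at 96.3 ± 115 CPM in DD and 10.5 ± 3.65 CPM in VD (229 CPM in DD 83 and at most 39.2 in the other DD libraries, and an edgeR call lost without DD 83, adjusted p = 0.928), C54G4.5 (2.78 ± 0.42), C41G7.7 (2.39 ± 0.49), ZK849.1 (2.36 ± 0.53), K04C2.3 (1.90 ± 0.39), rabr-1 (1.88 ± 0.38) and T12B3.7 (1.85 ± 0.41) were also higher in DD. The lower genes included cup-4, whose product acts in coelomocyte uptake, at 4.21 ± 2.22 CPM (SD, n = 3) in DD and 113 ± 101 CPM (SD, n = 4) in VD, and lgc-26 (-5.04 ± 0.88), lgc-28 (-5.18 ± 0.99), zip-8 (-5.45 ± 1.03), Y116A8C.3 (-4.86 ± 0.93), Y73F4A.1 (-4.73 ± 0.92), clec-178 (-4.62 ± 0.71) and T19C3.5 (-4.56 ± 0.73). Coelomocyte genes had 0 of 3 genes higher and 3 lower (0 and 3 over the list, adjusted p = 6.71e-17, or 0.00236 with estimated correlation), and 13 of the 15 genes lower in DD were highest in VD 78.

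The transcription factor genes unc-55 and irx-1 differed between DD and VD by -1.29 ± 0.41 and 1.83 ± 0.44 without passing (edgeR adjusted p = 0.430 and adjusted p = 0.0866), and the VD marker list was called higher in DD, with a median log2 difference of 0.75 and 0 of 11 genes higher and 0 lower (1 and 1 over the list, adjusted p = 1.55e-04, or 0.0807 with estimated correlation). On both marker lists, unc-30, unc-25, unc-47 and unc-46 differed by 0.96, 0.83, 0.79 and 0.84, also without passing. In all, 28 of 15181 genes passed, 13 higher and 15 lower in DD, and 684 had an unadjusted p under 0.05. The DD against VD count was 11 without DD 83, 13 without DD 84, 8 without DD 86, 13 without VD 77, 5 without VD 78, 14 without VD 79 and 17 without VD 81, and 91 (60 higher and 31 lower) with the DESeq2 test, 2 (2 higher and 0 lower) with these groups fitted alone, 53 (31 higher and 22 lower) without AWA 20 and AWB 51. The DD against VD calls split into 17 higher and 13 lower without mitochondrial and rRNA genes, 18 higher and 14 lower with no low-count filter. In edgeR flp-13 was not called without DD 83 or 86 (2.01 to 2.34, adjusted p from 0.0945 to 0.226) or VD 77, 78 or 79 (2.21 to 2.34, adjusted p from 0.0985 to 0.149). Of the 16 genes named by rank, the number no longer called was 9 without DD 83, 9 without DD 84, 12 without DD 86, 7 without VD 77, 13 without VD 78, 7 without VD 79 and 5 without VD 81. C54G4.5 kept its call in each of these.

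**Figure D2:**
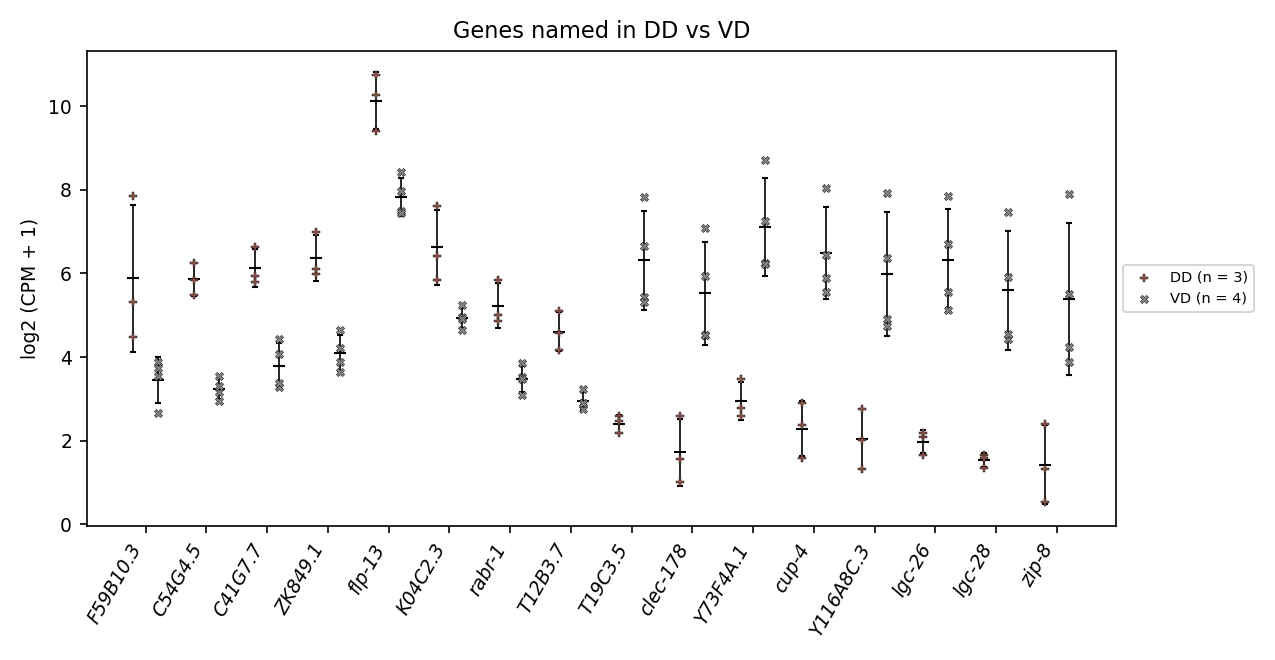
log2 (CPM + 1) of the 16 genes named by rank between DD and VD, with 1 point per library, the mean and the SD as bars. The 8 genes on the left are higher in DD and the 8 on the right are higher in VD, where the highest point of each is VD 78.

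AWA and AWB, the olfactory neuron pair, were compared directly. odr-10 stood at 5743 ± 5236 CPM (SD, n = 4) in AWA and 25.6 ± 15.3 CPM (SD, n = 5) in AWB, and ocr-1 at 849 ± 371 and 2.19 ± 2.36 CPM (log2 differences 7.78 ± 1.04 and 8.36 ± 0.82, SE). AWA markers had 7 of 8 genes higher and 0 lower (7 and 0 over the list, adjusted p = 4.44e-14, or 0.206 with estimated correlation). AWB markers had 0 of 11 genes higher and 7 lower (0 and 8 over the list, adjusted p = 4.83e-16, or 0.240 with estimated correlation). lim-4 (-6.35 ± 0.73), odr-1 (-7.69 ± 0.82), daf-11 (-6.74 ± 0.78), tax-2 (-6.44 ± 0.70) and srd-23 (-8.63 ± 1.20) were lower in AWA, and str-220, with no counts in AWA, was at least 2165-fold lower. odr-3 (-0.07 ± 0.63), which is on both lists, and ceh-37 (-0.05 ± 0.52) did not pass.

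Insulin-like peptide, cilium and intestine genes were called higher in AWA than AWB, with 15 of 27, 13 of 44 and 6 of 17 genes higher and 3, 0 and 0 lower (17, 14 and 6 higher and 4, 0 and 0 lower over the list). As lists they had adjusted p from 5.41e-09 to 0.0415, and from 0.375 to 0.870 with estimated correlation. Without AWA 20 the direction of the intestine list reversed (adjusted p = 0.870), and its call also ended without AWB 50 or AWB 53 (adjusted p = 0.0866 and 0.0571). Guanylyl cyclase, hypodermis, coelomocyte, body-wall muscle and stress response genes were called lower, with 0 of 27, 0 of 20, 0 of 3, 0 of 21 and 0 of 13 genes higher and 6, 5, 2, 0 and 4 lower (1, 0, 0, 0 and 0 higher and 7, 5, 2, 0 and 4 lower over the list). Tested as lists these had adjusted p from 4.58e-04 to 0.00840, and from 0.240 to 0.519 with estimated correlation. The body-wall muscle call ended without AWB 51 (adjusted p = 0.175). The chemoreceptor genes sre-15 and str-148, the nuclear receptor genes nhr-222 and nhr-175, and C04C3.6, F11A5.15 and T01G6.10 had no counts in AWB and were higher by at least 129.7, 82.9, 58.1, 49.5, 82.3, 61.8 and 61.6 times. Without AWA 17 the limits were 37.9 for str-148, 32.7 for F11A5.15 and 43.4 for srt-14. srt-14, also with no counts in AWB and at least 75.7-fold higher, did not pass the DESeq2 test. srg-64, str-240 and Y64G10A.2 had no counts in AWA and were lower by at least 216, 134 and 148 times. R02D5.6 differed by -9.54 ± 1.10, srt-62 had a count ratio of 2411 (95% interval 432 to 95343) and sru-39 a count ratio of 753 (95% interval 134 to 29843), both in favour of AWB. Of 15181 genes, 2450 passed in edgeR, 1413 higher and 1037 lower in AWA. The AWA against AWB count was 1510 without AWA 17, and 799 with these groups fitted alone. The AWA against AWB calls split into 1233 higher and 1371 lower with the DESeq2 test.

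**Figure D3:**
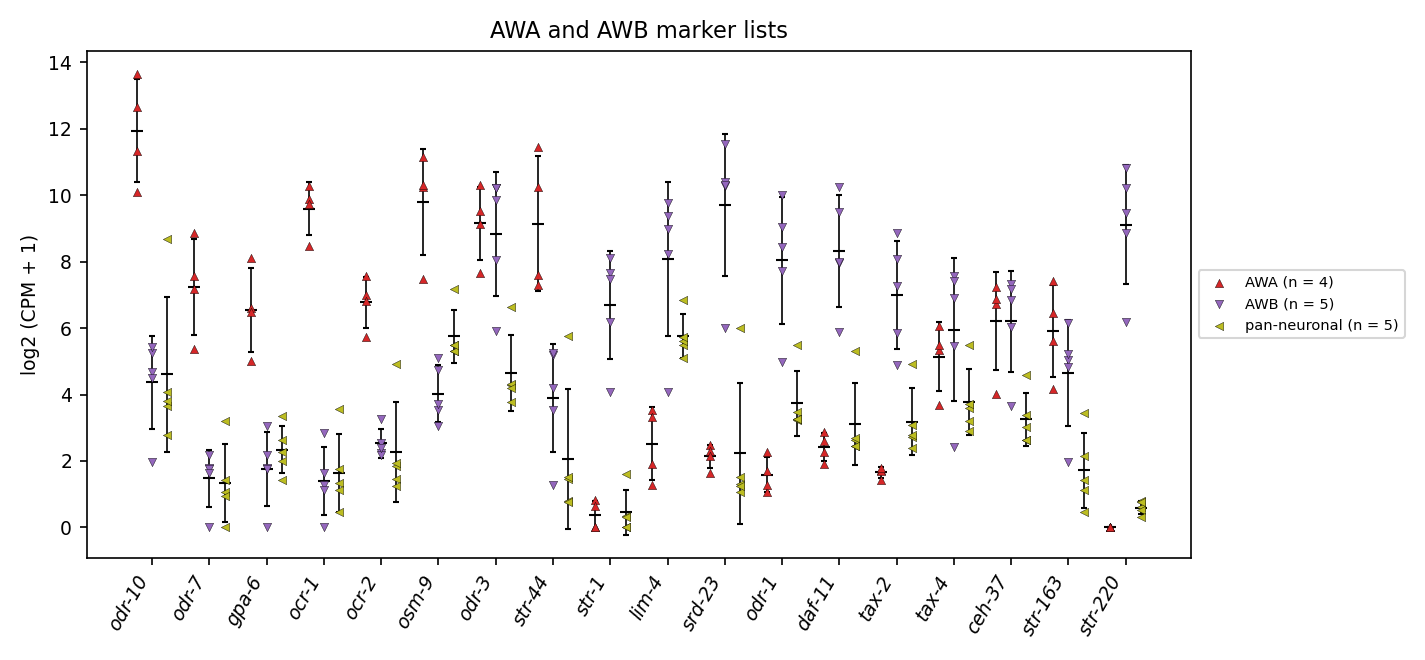
log2 (CPM + 1) of the AWA and AWB marker genes in AWA, AWB and pan-neuronal libraries, with 1 point per library, the mean and the SD as bars. The AWA points lie above the AWB points for odr-10, odr-7, ocr-1, ocr-2, osm-9 and gpa-6, and below them for str-1, lim-4, srd-23, odr-1, daf-11, tax-2 and str-220.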

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

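The tests of the flanking genes, of the coelomocyte genes and of the non-coding RNA genes, the unc-54 value without all-cell 27, and the regrouping of libraries for pan-neuronal against all-cell and DD against VD, were chosen only after the result was seen. In groups of 4 or 5 libraries, 1 library was set apart by its gap to the next in 58 of 344 group values. In 17 of them the others were all at 0, where any count sets a library apart, so the rate of about 1 in 20 that chance gives does not apply to these. The range of the other libraries of the group follows each value in brackets. Pan-neuronal 1 stood apart in 20 values. As shares of counts these were pan-neuronal 3.70% (3.01 to 3.08), pharyngeal muscle 0.0269% (0.0129 to 0.0149), hypodermis 0.0589% (0.114 to 0.127), glia 0.0194% (0.00712 to 0.00901), mitochondrial 1.07% (1.81 to 2.08) and stress response 0.152% (1.09 to 1.42). As levels they were F46A8.7 1413 CPM (154 to 186), T20G5.8 2.64 CPM (0.646 to 1.12), phat-7 18.2 CPM (9.05 to 11.5), rbm-3.1 7.92 CPM (19.3 to 23.3), T22F3.11 77.6 CPM (40.2 to 47.8), acbp-7 185 CPM (93.3 to 117), Y116A8C.40 0.264 CPM (0), ocr-1 10.8 CPM (0.372 to 2.40), srt-7 4.22 CPM (0 to 0.431), srj-11 5.81 CPM (0), B0432.1 7.92 CPM (1.12 to 2.40), nlp-23 5.02 CPM (0 to 0.473), srt-12 9.24 CPM (0.431 to 2.98) and ttx-3 35.9 CPM (11.9 to 18.5). All-cell 27 had the shares 10 most abundant genes 8.92% (5.80 to 6.18), pan-neuronal 1.42% (0.495 to 0.581) and stress response 0.267% (0.0634 to 0.0723), and the levels C18A3.16 0.840 CPM (0), C18A3.20 0.840 CPM (0) and C06E1.7 3802 CPM (2.43 to 4.53). VD 78 had 10 most abundant genes 5.62% (4.06 to 4.30), snf-11 39.99 CPM (19.8 to 22.8), F33H12.7 48.9 CPM (8.75 to 14.2), zip-8 239.9 CPM (13.7 to 44.3) and cof-2 156 CPM (17.03 to 34.0). AWA 20 had the shares pan-neuronal 0.614% (1.54 to 1.63), intestine 1.58% (0.00737 to 0.260) and coelomocyte 0.00156% (1.12e-04 to 2.93e-04), and AWB 51 unc-54 share 0.896% (0.268 to 0.417), body-wall muscle 3.89% (0.959 to 1.75) and pharyngeal muscle 0.407% (0.0171 to 0.0612). ASG 16 had the shares hypodermis 0.314% (0.0744 to 0.0964) and sperm 0.0227% (0.00159 to 0.00253). Pan-neuronal 11 had low levels of genes with no counts in the others, F44D12.16 0.236 CPM (0), ZK177.9 0.236 CPM (0), M163.15 0.946 CPM (0), K09C4.7 0.473 CPM (0), C02D4.6 0.709 CPM (0) and C02D4.7 0.709 CPM (0). Single levels stood apart in VD 79 (unc-30 189 CPM, others 380.4 to 399), all-cell 29 (F46A8.7 0.566 CPM, others 0), all-cell 30 (K11C4.8 0.485 CPM, others 0), all-cell 28 (ZK265.11 54.4 CPM, others 16.98 to 22.7), ASG 13 (scl-8 95.2 CPM, others 32.1 to 41.2), ASG 15 (C18A3.20 0.528 CPM, others 0), pan-neuronal 7 (C06E1.12 0.431 CPM, others 0), AWA 17 (nlp-23 480.3 CPM, others 45.1 to 118, C18A3.16 0.764 CPM, others 0, R02D5.6 5.34 CPM, others 0.556 to 1.13), pan-neuronal 12 (str-1 2.06 CPM, others 0 to 0.264), AWA 18 (srt-62 0.556 CPM, others 0, sru-39 0.556 CPM, others 0). Tested between groups, the difference from pan-neuronal libraries was unlike in 28 genes between DD and VD and in 2450 genes between AWA and AWB.

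Libraries of each comparison with at least 3 per group were also regrouped into groups of the real sizes (40 groupings, or 35 where there are no more, the real one included) and genes called again; the real count and the highest of another grouping follow. The real count was highest for pan-neuronal against all-cell libraries (8966 and 5599). Against pan-neuronal libraries it was highest for ASG (5709 and 171), AVE (5101 and 199), AVG (4768 and 82), AWA (5744 and 2892), AWB (6634 and 394), DD (5936 and 47) and VD (8538 and 4838), against all-cell libraries for ASG (6048 and 2801), AWB (5098 and 4013) and VD (3243 and 698), and against other types for ASG (4507 and 3348), AVE (2083 and 676), AVG (1748 and 986), AWA (2694 and 1285), AWB (2635 and 1408) and VD (3145 and 1559). Another grouping called more genes against all-cell libraries for AVE (2327 and 3152), AVG (3065 and 3531), AWA (4926 and 5327) and DD (2915 and 3462), and for DD against other types (832 and 1371), DD against VD (28 and 47) and AWA against AWB (2450 and 3832). So few groupings cannot exclude chance. For AWA against AWB this concerns the count alone, as ocr-1 (8.36 ± 0.82), osm-9 (6.08 ± 0.64) and odr-1 (-7.69 ± 0.82) differed with no overlap of libraries. Groupings that call many genes point to sample structure. In those of AVE, AVG and DD with all-cell libraries, all-cell 27 stood with the type, apart from all-cell 28, 29 and 30. In those of AWA, all-cell 27 or AWB 50 stood with AWA 17, 18 and 19, while AWA 20 stood with the other group. AWA 20 had a mean correlation across genes of 0.850 with VD, 0.826 with DD and 0.768 with the other AWA libraries, and AWB 51 of 0.850 with VD and 0.747 with the other AWB libraries.

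Some transcripts next to another gene were high in a single sorted group: C18A3.16 at rab-3 in pan-neuronal libraries, C06E1.7 at glr-1 and T27A3.11 at pept-3 in AVE, F33D4.11 at flp-13 in DD, and C02D4.6 at ser-2 and T01B7.11 at rol-6 in PVD. Transcription together with the host gene stays open: the log2 ratio of flank to host exceeded that in the group with the highest other host level by at least 2.69, but the loci were picked for flanks high in 1 group, which sets most of that difference. Reporter constructs that carry the 5' flank of marker genes may be a source, but across all markers 28 of 67 genes within 6 kb on the 5' side and 24 of 72 on the 3' side were higher in the type (one-sided Fisher's exact p = 0.196), which leaves this open. Many copies of rab-3 sequence in the pan-neuronal strain remain open as well: the rab-3 difference from the types was 2.84, against a mean of 0.96 and at most 2.08 over 27 other pan-neuronal genes, 2.74 SDs above their mean. All-cell 27 held C06E1.7, fip-3 and C06E1.12 at 3802, 638 and 173 CPM (AVE means 4303, 430 and 169), T27A3.11 at 0, and had a mean correlation of 0.883 with AVE and 0.852 with the other all-cell libraries; a mixed or mislabelled sample was not tested and stays open.

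Genes lower in DD than VD included the coelomocyte genes cup-4, unc-122 and lgc-26, with means of 113, 63.2 and 103 CPM in VD against 29.5, 12.05 and 19.3 CPM in all-cell libraries, and 13 of the 15 were highest in VD 78; with DD and VD fitted alone none of the 15 was called. Coelomocytes that passed the VD sort gate are a candidate source: relative to the coelomocyte list, the other 12 genes had a median log2 difference of -0.16 (interquartile range 0.82) between VD and all-cell libraries. An unc-122 reporter alone is argued against, since cup-4 and lgc-26, fixed with unc-122 in the list, differed between VD and DD by 4.81 ± 0.89 and 5.04 ± 0.88 (SE) and unc-122 by 4.31 ± 0.83. Expression in the VD neurons themselves stays open: the SD of the coelomocyte list over the 4 VD libraries was 3.55 times that of the VD markers (1.21 and 0.34 log2), which expression that varies between preparations could also give. Of the list, 3 genes are among the 15, and how many of them VD neurons express is not known from these libraries.

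Non-coding RNA genes were mostly higher in pan-neuronal than all-cell libraries, 439 of 613 tested against 34 lower. With every library thinned to 251586 counts, 64 were higher and 15 lower, 4.27 to 1; as most genes of this class then fell below the filter, a part played by depth cannot be told apart. Reads of overlapping protein-coding genes as the whole cause are argued against, since 63.6% of tested genes without such an overlap were higher, against 75.9% with one. VD libraries, with a median total 3.63 times that of all-cell libraries, had 23 such genes higher and 29 lower than all-cell libraries (0.793 to 1), which argues against depth as the whole cause. A difference between neurons and other cells could add to the excess, as the other 7 types had 45 to 113 higher and 6 to 31 lower than all-cell libraries, but each of the 8 types, neurons too, also had 20 to 64 higher and 281 to 453 lower than pan-neuronal libraries.

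The ratio of unc-54 to other body-wall muscle genes was 1.14 log2 units higher in sorted neuron than all-cell libraries (SE 0.82), and 1.91 (SE 0.31) without all-cell 27, whose ratio was 6.09 against 2.70 to 3.45 in the others. Group means ran from 3.61 in VD to 6.61 in pan-neuronal libraries, and reporter reads with an unc-54 3' end stay open.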

How the results depend on the processing

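Leaving out AWA 20 and AWB 51 together, and the list tests without single libraries, were chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because no groups share replicate numbers. Of the counts of called genes or tests under an alternative, 547 lay within 1.5 times the value in the report and 54 did not. The 457 list calls over all comparisons, each under 5 alternatives, kept their direction and side of the threshold 1845 times, lost the call 438 times and reversed 2 times. Without 1 library at a time these were 5608, 246 and 1, the last being the intestine list between AWA and AWB (adjusted p = 0.0415, and from 0.00178 without AWA 17 to 0.870 without AWA 20). Over all alternatives, named genes had 15962, 315 and 3, and 496 group shares moved by under 1 SD and 1 by more. An estimated correlation left 75 list calls. Fitted alone, groups gave these counts of called genes: against pan-neuronal libraries AVE 7762 and PVD 5569, against all-cell libraries ASG 4002, AVG 1384, AWA 2172, AWB 2860, DD 1724 and PVD 1332, DD against VD 2 and AWA against AWB 799. Such fits estimate the spread from fewer libraries and other tested genes. The DESeq2 test called 1314 genes for DD against the other types and 91 for DD against VD. With no low-count filter 13265 genes differed between VD and pan-neuronal libraries. Without AWA 20 and AWB 51 the counts against other types were 1582 for DD and 5218 for VD, and 53 genes were called for DD against VD. Without 1 library at a time, counts ran for PVD 965 (without PVD 62) to 3146 (pan-neuronal 1) against pan-neuronal libraries. Against all-cell libraries they ran for AVE 986 (without AVE 40) to 3474 (all-cell 27), AVG 1801 (without AVG 45) to 3713 (all-cell 27), DD 1369 (without DD 83) to 3671 (all-cell 27), PVD 838 (without PVD 63) to 3535 (all-cell 27) and VD 1507 (without all-cell 29) to 3671 (all-cell 27). Against the other types they ran for AVE 1012 (without AVE 40) to 2283 (AWA 20), AVG 986 (without AVG 45) to 2044 (AWA 20), DD 427 (without DD 83) to 1155 (AWA 20), PVD 371 (without PVD 63) to 928 (AWB 51) and VD 1908 (without VD 77) to 4489 (AWA 20). For DD against VD they ran 5 (without VD 78) to 17 (VD 81), and for AWA against AWB 1510 (without AWA 17) to 3570 (AWA 20). With PVD at 1 library, that library is assumed to vary like the other groups. The 36 share tests that passed became 14 to 40. Reversed were vit-4 (log2 difference -2.86, and 3.43 with edgeR adjusted p = 0.0308 without all-cell 27, otherwise down to -3.31) and vit-3 (-2.80, and 4.77 with adjusted p = 0.00933, otherwise down to -3.26), both for pan-neuronal against all-cell libraries, and fat-6 for PVD against pan-neuronal libraries (2.82, and -0.06 without PVD 62, otherwise up to 3.51). With no low-count filter the chemoreceptor list reversed in AWA (adjusted p = 0.909) and AWB (adjusted p = 0.942) against pan-neuronal libraries. For all these, beyond what fewer samples and genes bring, the cause was not tested. Alternatives that turned the majority of calls to the other direction stand with their splits in the report. Leaving out 1 library also turned it: for VD against pan-neuronal libraries without VD 77 or 79, against all-cell libraries for ASG without ASG 13, 14 or all-cell 27, AVG without all-cell 28, AWA without AWA 20 and AWB without AWB 50, 52, 53, 54 or all-cell 27, for VD against other types without ASG 13, 14, AVG 44, 45, AWB 50, 52, 53 or 54, and for DD against VD without DD 84 or 86. The median log2 difference of all genes moved by -0.56 (ASG against all-cell) to 0.36 (PVD against pan-neuronal) with library totals alone, by -0.20 to 0.17 with DESeq2 size factors and by -0.31 to 0.19 without mitochondrial and ribosomal RNA genes. At these depths and group sizes, simulated 2-fold changes were recovered in 0% to 5.68% of genes.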

Other observations

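The list tests described here were planned, and only the choice of lists to describe followed from their results. Ionotropic glutamate receptor genes were called higher in the interneurons AVE and AVG when each was set against the other 7 types. In AVE they had 8 of 12 genes higher and 0 lower (9 and 0 adjusted over the list alone, adjusted p = 3.05e-07, or 0.153 with an estimated correlation). In AVG they had 6 of 12 genes higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 2.59e-12, or 0.379 with an estimated correlation). Genes of acetylcholine synthesis and transport had 5 of 6 genes higher and 0 lower (5 and 1 adjusted over the list alone, adjusted p = 2.99e-04, or 0.125 with an estimated correlation) in AVE. Each of these calls was lost with the estimated correlation. These are not independent of the marker lists: the AVE markers hold glr-1, glr-2, nmr-1, nmr-2, unc-17 and cho-1 of them, and the AVG markers glr-1, nmr-1, unc-17 and cho-1.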
